A study of Schizosaccharomyces pombe with 40 samples.

How the data were processed

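Total RNA of fission yeast (Schizosaccharomyces pombe) was measured on 40 two-colour arrays. Per the labels, 4 strains carrying truncations or a site mutation of rep2 (Cdelta21, Cdelta53, Cdelta94 and 2C/S-H/Y) were grown in rich medium at mid log phase and sampled at 0, 10, 30, 60 and 120 min in 8 mM hydroxyurea, with 2 arrays for each strain and time. Hydroxyurea inhibits ribonucleotide reductase and stalls DNA replication. Per the labels' protocols, RNA was extracted with hot phenol, reverse transcribed with aminoallyl-dUTP and coupled to dye. The strain's RNA carried Cy5 and a pooled wild-type mid-log reference carried Cy3 on all 40 arrays, so there was no dye swap and no array of wild-type cells as a sample. The description field of the samples also names another mutant, and the strain names were taken from the sample titles. Nothing in the labels says that the 2 arrays of a group came from separate cultures, so p-values measure the spread between these arrays, which may be technical.

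The values used were the authors' deposited table of log2 ratios, 1 value per probe and array, and nothing was added to or subtracted from them before the tests. The base was settled from the values: 2 to the power of the value was a whole multiple of 0.001, within 0.02 of that unit, for 100% of the values below 0, against 3.48% with base 10 and 5.51% with base e. The direction of the ratio is not stated; it was taken as Cy5 over Cy3, that is strain over wild-type reference. Array medians ran from −0.12 to 0.06, and the lowest correlation between any pair of arrays across probes was −0.05. The scanner, the background correction and the normalization are not given in the sources used here, and neither signal intensities nor spot quality were used. Of all values, 1.17% were missing.

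Of 9858 probes, 9632 had 1 gene symbol in the platform annotation, 44 had several and 182 had none. All 4816 genes with a symbol of their own had 2 probes, which were averaged per array; probes with several or no symbol were kept apart and were not named. Features were kept if they had a value on at least 80% of the arrays and on at least 1 array of every group. The others were left out (38 of 5042), which left 5004 for testing, 4794 of them named genes. Of the annotated genes, 99.5% were found in the RefSeq gene table of assembly ASM294v3, which served for current names and for the order of neighbouring genes only.

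Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes on the means of the 20 groups, with 20 residual degrees of freedom), and p-values were adjusted by the Benjamini-Hochberg method over the 5004 features tested, with a threshold of 0.05. "Rose", "fell", "higher" and "lower" refer to an adjusted p under that threshold in this test. All standard errors (SE) are limma's, on the log2 scale. The comparisons were hydroxyurea at each time against 0 min as the mean over the 4 strains with equal weight, the time course within each strain (F test), the difference of the time courses between strains (interaction F test), each pair of strains at 0 min, and each strain at 0 min against the wild-type reference. The reference stands as 1 control in that last comparison, which leaves out the spread of the control and any effect of the dyes. Strain and any batch of cultures or slides cannot be told apart, because the labels give no batch. The number of arrays limits the precision.

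Gene lists, the rule for naming genes, the tests and the first set of alternatives were fixed before the data were examined. The 23 lists were tested with camera (preset correlation between genes 0.01, and again with an estimated correlation) and fry. Before these tests 142 missing values were replaced by the gene's mean in the same group, that is by the value of the other array. The adjusted p given for a list is camera's with the preset correlation unless said otherwise, adjusted over the lists of that comparison. Counts of list members are given over all features tested and, where they differ, adjusted over the list alone. The mitochondrially encoded list had 0 members on the array and the Tf2 list 1 (Tf2-11), so 21 lists were tested; the result of 1 of them is not reported here. The pattern that defines the ribosomal protein list also takes rpp1, an RNase P subunit. For the targets of MBF, the transcription complex that Rep2 activates, the mean log2 ratio of the 20 matched genes was compared between strains with an exact two-sided permutation test that exchanged arrays within each time (7776 regroupings, 6 pairs of strains, Benjamini-Hochberg adjustment); yox1 was on the list and was not matched.

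Named genes were, for hydroxyurea against 0 min, up to 12 with the largest rise and 8 with the largest fall among those past the threshold and with the same sign in all 4 strains; for each time course, the 3 with the smallest p; for the interaction, the 10 with the smallest p; for each pair of strains and each comparison with the reference, the 5 largest in each direction; for each list, up to 4 members with the largest change past the threshold; and rep2, rep1, res1, res2, cdc10, cdc22, cdc18, cig2, cdt1, mik1, nrm1, yox1 and suc22 whatever their values. The text gives a part of them.

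The procedure was tested on simulated data for the same 5004 features. For the mean response at 120 min, 57 of 67 genes changed by 1.25-fold were recovered, and all 67 changed by 1.5-fold; 5% of the 200 genes called were unchanged. For Cdelta21 against Cdelta94 at 0 min, 14 of 67 genes changed by 1.25-fold, 50 of 67 changed by 1.5-fold and all 66 changed by 2-fold were recovered, and 4.41% of the 136 genes called were unchanged. Of 100 random lists of 20 genes, 0 reached a camera p under 0.05. The simulated values were drawn independently across genes and arrays, with 1 spread per gene for all arrays. The list result therefore says nothing about lists whose genes move together. In the real arrays the SD of the difference within replicate pairs was 0.07 to 0.10 in Cdelta53 and 0.22 to 0.44 in Cdelta94. Neither this unequal spread nor near-repeat arrays were simulated, so the shares recovered and unchanged need not hold for the real data. Arrays with the same replicate number deviated from their group means with correlations above 0.1 in 5, 3, 5 and 8 of the 10 pairs of times in Cdelta21, Cdelta53, Cdelta94 and 2C/S-H/Y, with a consensus correlation of 0.145. The numbers were not taken to pair the arrays, as not every pair was above 0.1, and the replicate block was kept as an alternative. Alternatives were a replicate block, a random block for each strain's numbered time course, robust empirical Bayes, median centring and quantile normalization between arrays, probes kept apart, other filters on missing values, fits with only the groups compared, and leaving out each array in turn. Counting near-repeat arrays once and leaving out the Cdelta94 arrays labelled 30 and 120 min were added after the data were seen.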

Results

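Gene expression was measured in 4 fission yeast strains with altered rep2 through a 120 min hydroxyurea time course. Rep2 is an activator of MBF, the complex that drives transcription of G1/S genes. The strains were Cdelta21, Cdelta53 and Cdelta94, which per the labels carry truncated rep2, and 2C/S-H/Y, which carries a site mutation. Each strain was sampled at 0, 10, 30, 60 and 120 min with 2 arrays per time, 10 per strain and 40 in all. Every array gave the log2 ratio of the strain to a pooled wild-type reference for 5004 features tested. As arrays, their number limits the precision.

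The signal at the rep2 probes separated the strains. Its 2 probes on the array were read apart, each as mean ± SD over the 10 arrays of a strain. In Cdelta94 both were far below the wild-type reference, at −5.19 ± 0.24 for probe 1 and −5.09 ± 0.44 for probe 2. Signals at or near background were not told apart, so ratios this low give no exact fold. In Cdelta53 the probes differed, with −1.36 ± 0.23 for probe 1 and −4.68 ± 0.34 for probe 2. In Cdelta21 both were moderately low, at −0.70 ± 0.14 and −0.90 ± 0.23. In 2C/S-H/Y probe 1 was at 0.63 ± 0.24 and probe 2 at −0.10 ± 0.27. The place of each probe within the gene is not given, and the gene-level values below average the probes. Whether a truncation removes the sequence that a probe reads is not known. Values of rep2 here and below are therefore signal at the probes and not the level of the transcript.

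**Figure D1:**
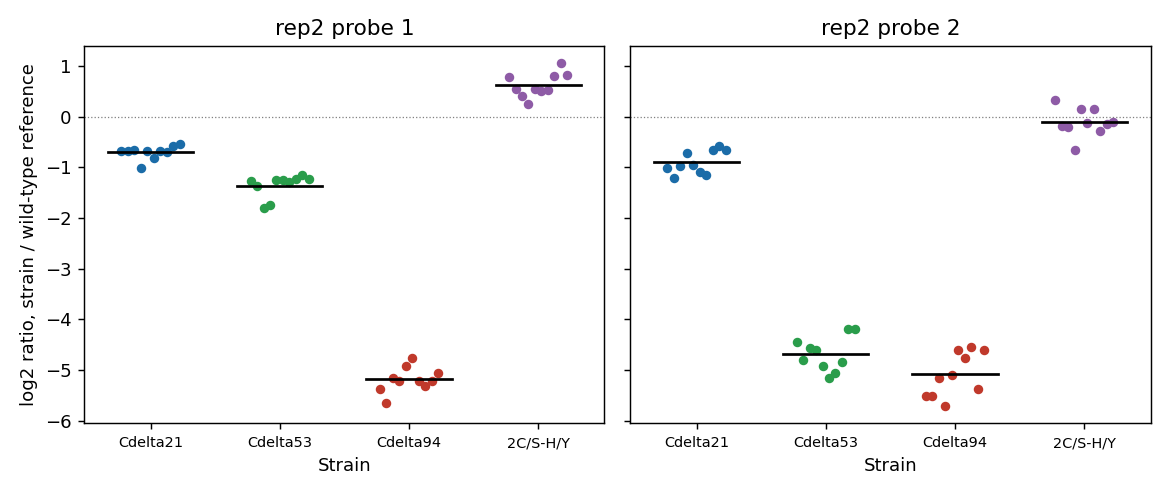
Log2 ratio of rep2 (strain over wild-type reference) for each of the 2 probes; points are arrays and bars the mean of 10 arrays per strain. Both probes lie near −5 in Cdelta94, and in Cdelta53 probe 2 (mean −4.68) lies far below probe 1 (mean −1.36).

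At 0 min, averaged over its probes, rep2 was lower than the reference in Cdelta21 by a log2 ratio of −0.89 (SE 0.10, n = 2 arrays, adjusted p = 5.48e-08). It was also lower in Cdelta53 (adjusted p = 1.44e-18), where probe 1 stood at −1.32 and probe 2 at −4.62, and in Cdelta94 (adjusted p = 8.03e-26), where both stood at −5.51. The values of Cdelta53 probe 2 and of Cdelta94 may lie at background, and the truncated genes may lack the sequence read. They give no exact size and do not show the level of the transcript. In 2C/S-H/Y it was higher at 0.37 (adjusted p = 0.00339), a call that was lost without the 0 min replicate 1 array of that strain, where rep2 stood at 0.19 (adjusted p = 0.314).

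The first question was how the targets of MBF stood in each strain. Over the whole time course, the mean log2 ratio of the 20 MBF targets was 0.35 in Cdelta21, 0.06 in Cdelta53, −0.32 in Cdelta94 and 0.50 in 2C/S-H/Y. The MBF targets in Cdelta94 were lower than in Cdelta21 by 0.67, lower than in Cdelta53 by 0.38, and differed from 2C/S-H/Y by −0.82. Those of Cdelta53 were lower than in Cdelta21 by 0.29 and differed from 2C/S-H/Y by −0.44. Each of these 5 differences had the same sign at all 5 times and an exact two-sided permutation p of 0.000257 (adjusted p = 0.000309), the smallest that this test can give. The test takes all arrays as separate, also those of the same strain at different times. The arrays of a strain may come from the same cultures, so every p of this test may be too small. With 2 time courses per strain as the units, 2 against 2, the smallest p possible is 0.333. The Cdelta53 pairs nearly repeat each other, as described with the time courses, so the p-values that involve this strain may be too small for that reason as well. Cdelta21 differed from 2C/S-H/Y by −0.15, with the same sign at 4 of 5 times (exact permutation p = 0.00977, adjusted p = 0.00977). After quantile normalization that last difference was −0.0832 (adjusted p = 0.185).

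**Figure D2:**
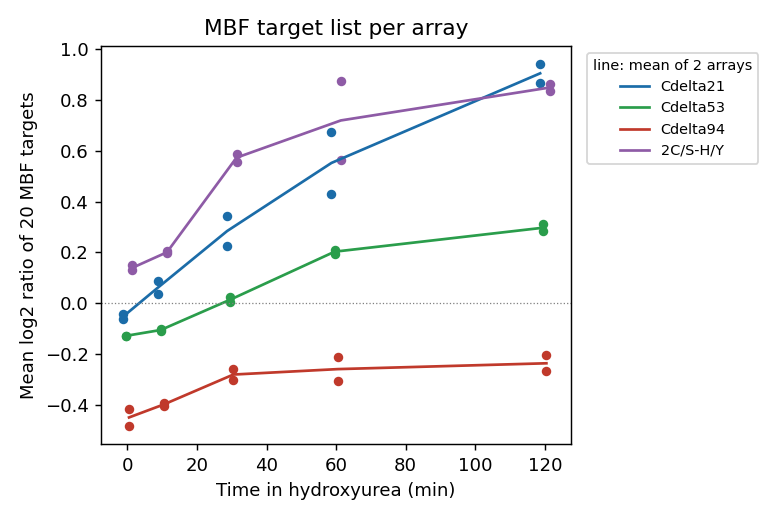
Mean log2 ratio (strain over wild-type reference) of 20 MBF targets against time in hydroxyurea (min), with a point per array and a line through the mean of 2 arrays. Cdelta94 runs from −0.45 at 0 min to −0.23 at 120 min, below the other 3 strains at every time.

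Before hydroxyurea, single MBF targets were already lower in Cdelta94 than in wild type. At 0 min cig2, an S-phase cyclin gene, stood at −2.37 (SE 0.10), mik1, a kinase gene of the replication checkpoint, at −1.51 (SE 0.11), and dut1, the dUTPase gene, at −1.44. In the same strain cdc22, the large subunit of ribonucleotide reductase, stood at −1.38 (SE 0.12), tos4 at −1.38 and cdc18, the replication licensing factor gene, at −1.30 (SE 0.14), all with n = 2 arrays. In Cdelta53 mik1 stood at −1.11, cig2 at −0.75 and cdc18 at −0.61. In Cdelta21 cdc22 was higher than in the reference at 0.60, while cig2 at −0.65 and mik1 at −0.53 were lower. In 2C/S-H/Y dut1 at 0.86, tos4 at 0.72 and cdc22 at 0.67 were higher. Of all 5004 features, 2698 differed from the reference in Cdelta21, 2864 in Cdelta53, 3371 in Cdelta94 and 2433 in 2C/S-H/Y. Calls among the MBF targets are therefore not by themselves particular to this list. Among all 20 targets 6 were higher and 9 lower than the reference in Cdelta21, 4 and 8 in Cdelta53, 4 and 11 in Cdelta94, and 8 and 2 in 2C/S-H/Y. In Cdelta53 the counts were 2 and 4 without either 0 min array and 1 and 4 with near-repeat arrays counted once. They were 4 and 5 in Cdelta21 without its 0 min replicate 1 array, and 5 and 0 or 6 and 0 in 2C/S-H/Y without replicate 1 or 2. As a list the MBF targets passed camera in none of the strains at this time, with adjusted p = 0.712, 0.426, 0.0722 and 0.249 in that order. By fry the adjusted p were 0.432, 0.0529, 1.69e-07 and 0.0188, so the list passed fry in Cdelta94 and 2C/S-H/Y.

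In hydroxyurea the MBF targets passed as a list at 120 min in all 4 strains with the preset correlation, and in Cdelta21 alone with an estimated one. The mean of the 20 targets moved from 0 to 120 min by 0.96 in Cdelta21, 0.42 in Cdelta53, 0.21 in Cdelta94 and 0.71 in 2C/S-H/Y. In Cdelta21 15 targets rose and 0 fell by limma (17 and 0 adjusted over the list alone; list adjusted p = 2.18e-15, and adjusted p = 0.00623 with an estimated correlation). Of the same targets 14 rose and 2 fell in 2C/S-H/Y (list adjusted p = 3.57e-05, and adjusted p = 0.0715 with an estimated correlation). In Cdelta53 10 rose and 1 fell (list adjusted p = 0.00182, and adjusted p = 0.257 with an estimated correlation), and 6 rose when near-repeat arrays, described with the time courses, were counted once. At 60 min, a time not in doubt, 1 target rose and 0 fell in Cdelta94 (2 and 0 adjusted over the list alone; list adjusted p = 0.00233, and adjusted p = 0.303 with an estimated correlation). Of the 20, 16 had a positive change there, and 8 were higher and 0 lower at an unadjusted p under 0.05. In the arrays labelled Cdelta94 120 min limma called 0 targets in either direction, 3 were higher and 0 lower at an unadjusted p under 0.05, and 19 of 20 had a positive change. The list passed there (adjusted p = 0.000636, and adjusted p = 0.185 with an estimated correlation). Without the 120 min replicate 1 array of Cdelta94, 1 target passed. In the arrays labelled Cdelta94 30 min 7 targets rose and 2 fell (7 and 3 adjusted over the list alone; list adjusted p = 0.174). The times of the Cdelta94 arrays labelled 30 and 120 min are in doubt, here and in the values that follow.

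From 0 to 120 min cdc18 rose by 2.64 in Cdelta21 (6.23-fold), 2.62 in 2C/S-H/Y (6.16-fold) and 1.74 in Cdelta53 (3.35-fold; SE 0.20 each, n = 2 arrays per time), and stood at 0.42 in Cdelta94 (adjusted p = 0.441). In the same order cdc22 rose by 1.69, 1.73 and 1.35, and stood at 0.25 in Cdelta94. The change of cig2 was 1.90 in Cdelta21, 1.88 in 2C/S-H/Y, 0.84 in Cdelta53 and 0.33 in Cdelta94. The difference between the strains was itself tested on the list. The response of the MBF targets at 120 min was larger in Cdelta21 than in Cdelta94 (median difference 0.69, 11 targets higher and 0 lower, 12 and 0 adjusted over the list alone, adjusted p = 3.29e-15, and adjusted p = 0.00698 with an estimated correlation). It was also larger in Cdelta21 than in Cdelta53 (median 0.49, 9 higher, adjusted p = 1.06e-05, but adjusted p = 0.145 with an estimated correlation). Cdelta94 and 2C/S-H/Y differed by a median of −0.46 (2 targets higher and 8 lower, 2 and 12 adjusted over the list alone, adjusted p = 0.000365, but adjusted p = 0.197 with an estimated correlation).

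**Figure D3:**
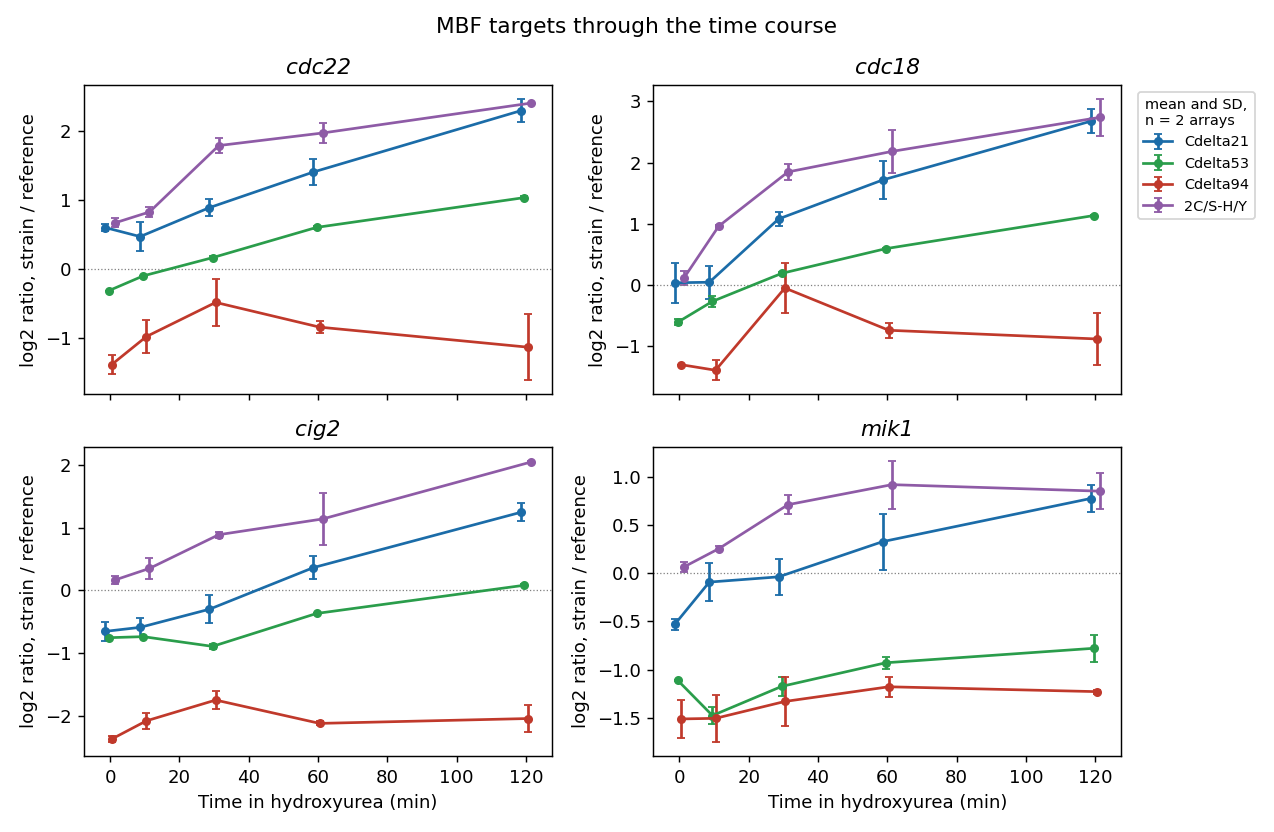
Log2 ratio (strain over wild-type reference) of cdc22, cdc18, cig2 and mik1 against time in hydroxyurea (min), as mean and SD of 2 arrays. In Cdelta94 the means of the 4 genes start at −1.38, −1.30, −2.37 and −1.51 and stay below the reference.

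The response to hydroxyurea was then averaged over the 4 strains (8 arrays per time) and compared with 0 min. At 10 min few genes had moved far. The gene rtc3 rose by 0.60 (SE 0.07, 1.52-fold, adjusted p = 1.21e-06), the superoxide dismutase gene sod1 by 0.40 and the iron uptake oxidase gene fio1 by 0.37, while the glycolytic gene tdh1 fell by 0.69 (adjusted p = 1.62e-06). Of 14 glycolysis genes 7 fell (9 adjusted over the list alone) and 0 rose (adjusted p = 5.44e-08, but adjusted p = 0.133 with an estimated correlation). Of 12 genes of the iron regulon 4 rose and 0 fell (5 and 0 adjusted over the list alone; adjusted p = 0.00167, and adjusted p = 0.0365 with an estimated correlation). Of 9 core histone genes 2 fell (4 adjusted over the list alone; adjusted p = 0.000863, but adjusted p = 0.331 with an estimated correlation). In the order Cdelta21, Cdelta53, Cdelta94 and 2C/S-H/Y the medians were −0.25, 0.09, −0.11 and −0.56 for glycolysis, −0.04, 0.13, 0.00 and 0.41 for the iron regulon and −0.25, −0.10, 0.05 and −0.40 for the core histones. Altogether 475 genes changed, 275 up and 200 down, 2 of them by at least 2-fold. By strain limma called 1158 genes at 10 min in 2C/S-H/Y (67 by at least 2-fold), 125 in Cdelta53, 109 in Cdelta21 and 4 in Cdelta94. The 0 and 10 min means of 2C/S-H/Y had a correlation across genes of 0.59. It was 0.83, 0.90 and 0.95 in Cdelta21, Cdelta53 and Cdelta94, and 0.92 between the 10 and 30 min means of 2C/S-H/Y. The 0 min arrays of 2C/S-H/Y thus stood apart from its later arrays, and all its changes from 0 min share them. A fast response and a shift of these 0 min arrays were not told apart. The count over the 4 strains was 844 after quantile normalization, 791 with the groups compared fitted alone and 714 with the replicate as a block. It was 309 without the Cdelta21 0 min replicate 1 array, 315 without the Cdelta53 0 min replicate 1 array and 77 with near-repeat arrays counted once.

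The means at 30 min include the arrays labelled Cdelta94 30 min, whose time is in doubt. At 30 min the uracil-regulated genes urg2 and urg1 had risen by 2.61 (SE 0.11, 6.10-fold, adjusted p = 1.88e-16) and 2.48 (5.58-fold). The ferric reductase gene frp1 rose by 1.99 (SE 0.06, 3.98-fold, adjusted p = 3.71e-20), the siderophore transporter gene str3 by 1.27, cdc18 by 1.21, the sulfiredoxin gene srx1 by 1.05 and the small heat shock gene hsp16 by 1.04. The RNA helicase gene dbp2 fell by 0.71, sap1 by 0.68 and the ribosome biogenesis gene mak16 by 0.55. Of 19 core stress response genes 14 rose and 0 fell (16 and 0 adjusted over the list alone; adjusted p = 3.84e-14, and adjusted p = 0.00172 with an estimated correlation). In the iron regulon 9 rose and 1 fell (10 and 1 adjusted over the list alone; adjusted p = 2.84e-10, and adjusted p = 3.88e-05 with an estimated correlation). Of 65 ribosome biogenesis genes 42 fell and 0 rose (46 adjusted over the list alone; adjusted p = 3.52e-13, and adjusted p = 0.00378 with an estimated correlation). The stress and ribosome biogenesis lists also passed in the arrays labelled Cdelta94 30 min alone, as given below, so these means rest in part on them.

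Also at 30 min, 8 of 9 core histone genes fell, by a median of −0.28 (9 adjusted over the list alone; adjusted p = 1.26e-05, but adjusted p = 0.0934 with an estimated correlation); hta2 fell by 0.48 and hhf2 by 0.42. The medians were −0.63 in Cdelta21, −0.43 in Cdelta53 and −0.39 in 2C/S-H/Y, and 0.23 in the arrays labelled Cdelta94 30 min. Of the MBF targets 12 rose and 3 fell (adjusted p = 1.41e-05, but adjusted p = 0.0934 with an estimated correlation). Of 10 genes of the Pap1 oxidative stress list 5 rose (adjusted p = 0.00497, but adjusted p = 0.0934 with an estimated correlation), with medians of −0.04, 0.01, 0.25 and 0.18 in Cdelta21, Cdelta53, the arrays labelled Cdelta94 30 min and 2C/S-H/Y. In all, 1338 genes changed at 30 min, 657 up and 681 down, 8 by at least 2-fold. With near-repeat arrays counted once the count was 603.

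At 60 min the rises were 2.44 for urg2, 2.32 for frp1, 2.31 for urg1, 1.39 for hsp16, 1.38 for cdc18 and 1.29 for hsp104, a disaggregase gene. The hexose transporter gene ght5 fell by 1.19, sap1 by 1.13 and the kinetochore gene cnp3 by 0.85. All 9 core histone genes fell, by a median of −0.37 (adjusted p = 2.88e-05, but adjusted p = 0.138 with an estimated correlation). Of the MBF targets 13 rose and 0 fell (adjusted p = 1.03e-10, and adjusted p = 0.0127 with an estimated correlation). Of 125 ribosomal protein genes 78 fell and 2 rose (89 and 2 adjusted over the list alone; adjusted p = 1.66e-12, but adjusted p = 0.459 with an estimated correlation), with medians of −0.43, −0.30, −0.35 and 0.04 in Cdelta21, Cdelta53, Cdelta94 and 2C/S-H/Y. The 2C/S-H/Y values at 60 min include replicate 1, which nearly repeats the 30 min replicate 1 array of that strain. At this time 1654 genes changed, 645 up and 1009 down, 20 by at least 2-fold. Counted once for near-repeats, 1009 changed.

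At 120 min 2413 genes changed, 1194 up and 1219 down, and 56 by at least 2-fold, 47 of them up. These means include the arrays labelled Cdelta94 120 min, whose time is also in doubt. Among genes with the same sign in all 4 strains the largest rise was that of frp1 at 2.67 (6.38-fold, adjusted p = 1.33e-23), followed by urg2 at 2.25 (4.77-fold) and SPOM_SPAC27D7.09C at 2.17. The replication licensing gene cdc18 rose by 1.86 (SE 0.10, 3.62-fold, adjusted p = 8.4e-15), gdh2 by 1.82 (3.54-fold), hsp104 by 1.75 (3.36-fold), the glutathione S-transferase gene gst2 by 1.62 (3.08-fold), cdt2 by 1.45, cdc22 by 1.26 (2.39-fold) and cig2 by 1.24 (2.36-fold). Among those that fell were dbp2 by 1.21 (adjusted p = 2.15e-12), the glucanase gene exg1 by 1.16, the amino acid permease gene aat1 by 0.93 and the ribosome biogenesis gene rlp7 by 0.93. Of the regulators, nrm1 rose by 0.24 and cdc10 by 0.31. The mean change of rep2 was 0.27 (adjusted p = 0.00285; after quantile normalization 0.125, adjusted p = 0.0855). By strain it was 0.31 in Cdelta21, 0.28 in Cdelta53, 0.44 in the arrays labelled Cdelta94 120 min and 0.04 in 2C/S-H/Y, with adjusted p = 0.12, 0.122, 0.188 and 0.838. As the largest of these comes from probes that may lie at background, the mean is not read as a rise of rep2. The changes of rep1 at 0.15 (adjusted p = 0.176) and res2 at −0.01 did not pass. The small ribonucleotide reductase subunit gene suc22 rose by 0.36, cdt1 by 0.81 and mik1 by 0.68.

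By list, 17 of 19 core stress response genes rose at 120 min and 0 fell (median 0.94, adjusted p = 1.04e-14, and adjusted p = 0.00138 with an estimated correlation), among them hsp16 at 2.41, ish1 at 1.30 and srx1 at 1.26. In the iron regulon 11 rose and 1 fell (median 0.53, adjusted p = 3.49e-07, and adjusted p = 0.00055 with an estimated correlation). Of the MBF targets 15 rose and 1 fell (median 0.57, adjusted p = 4.51e-08, and adjusted p = 0.0246 with an estimated correlation). Of 30 proteasome genes 23 rose and 1 fell (25 and 1 adjusted over the list alone; adjusted p = 1.55e-06, and adjusted p = 0.0246 with an estimated correlation), with rpt2 at 0.53 and rpn3 at 0.50. The ribosome biogenesis genes fell in 48 of 65 cases and rose in 0 (median −0.28, adjusted p = 1.19e-11, and adjusted p = 0.00672 with an estimated correlation).

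Other lists passed at 120 min with the preset correlation and not with an estimated one. Of 17 mitotic genes 10 fell and 2 rose (11 and 2 adjusted over the list alone; adjusted p = 0.00256, but adjusted p = 0.0513 with an estimated correlation), with the anaphase gene slp1 at −1.01 and spo12 at −0.69. Of the Pap1 list 7 rose (adjusted p = 0.00234, but adjusted p = 0.0586 with an estimated correlation; after quantile normalization adjusted p = 0.0827). Of 15 chaperone genes 8 rose (median 0.14, adjusted p = 0.0115, but adjusted p = 0.3 with an estimated correlation), and after quantile normalization their median was −0.0988 (adjusted p = 0.486). By strain the medians of the mitotic genes were −0.28, −0.40 and −0.38 in Cdelta21, Cdelta53 and 2C/S-H/Y and 0.15 in the arrays labelled Cdelta94 120 min. In the same order those of the Pap1 list were 0.22, 0.43, 0.46 and −0.01, and those of the chaperones −0.08, 0.15, 0.31 and 0.11. Of the ribosomal protein genes 53 fell and 3 rose (adjusted p = 4.51e-05, but adjusted p = 0.655 with an estimated correlation).

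The other lists reported here did not pass at 120 min by camera. By fry the core histones (adjusted p = 0.0502), DNA damage (adjusted p = 0.461) and copper transport (adjusted p = 0.29) lists did not pass. The other lists of this paragraph passed by fry, with a highest adjusted p of 0.0351. Of 9 core histone genes 4 rose and 1 fell (4 and 2 adjusted over the list alone, adjusted p = 0.29), of 31 replication machinery genes 4 rose and 7 fell (4 and 6 over the list alone, adjusted p = 0.291), of 27 DNA damage checkpoint and repair genes 4 rose and 7 fell (4 and 6 over the list alone, adjusted p = 0.541), and of 5 MBF machinery genes 3 rose (adjusted p = 0.162). The MBF machinery count includes rep2, whose change is not read as a rise for the reason given above. Mating and meiosis genes rose in 4 and fell in 5 of 17 cases (adjusted p = 0.541), glycolysis genes in 1 and 4 of 14 (adjusted p = 0.162), and respiratory chain genes in 3 and 10 of 25 (adjusted p = 0.155). Of 10 Sre1 genes 6 rose (adjusted p = 0.105), of 4 copper transport genes 1 rose and 2 fell (adjusted p = 0.661), of 6 phosphate and thiamine genes 2 rose and 3 fell (adjusted p = 0.476), and of 8 strain marker genes 4 rose (adjusted p = 0.162). The mean change of the retrotransposon Tf2-11 was 0.23 (adjusted p = 0.031), from 0.86 in Cdelta21, −0.05 in Cdelta53, 0.23 in Cdelta94 and −0.11 in 2C/S-H/Y. In the arrays labelled Cdelta94 30 min it had changed by −1.29.

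**Figure D4:**
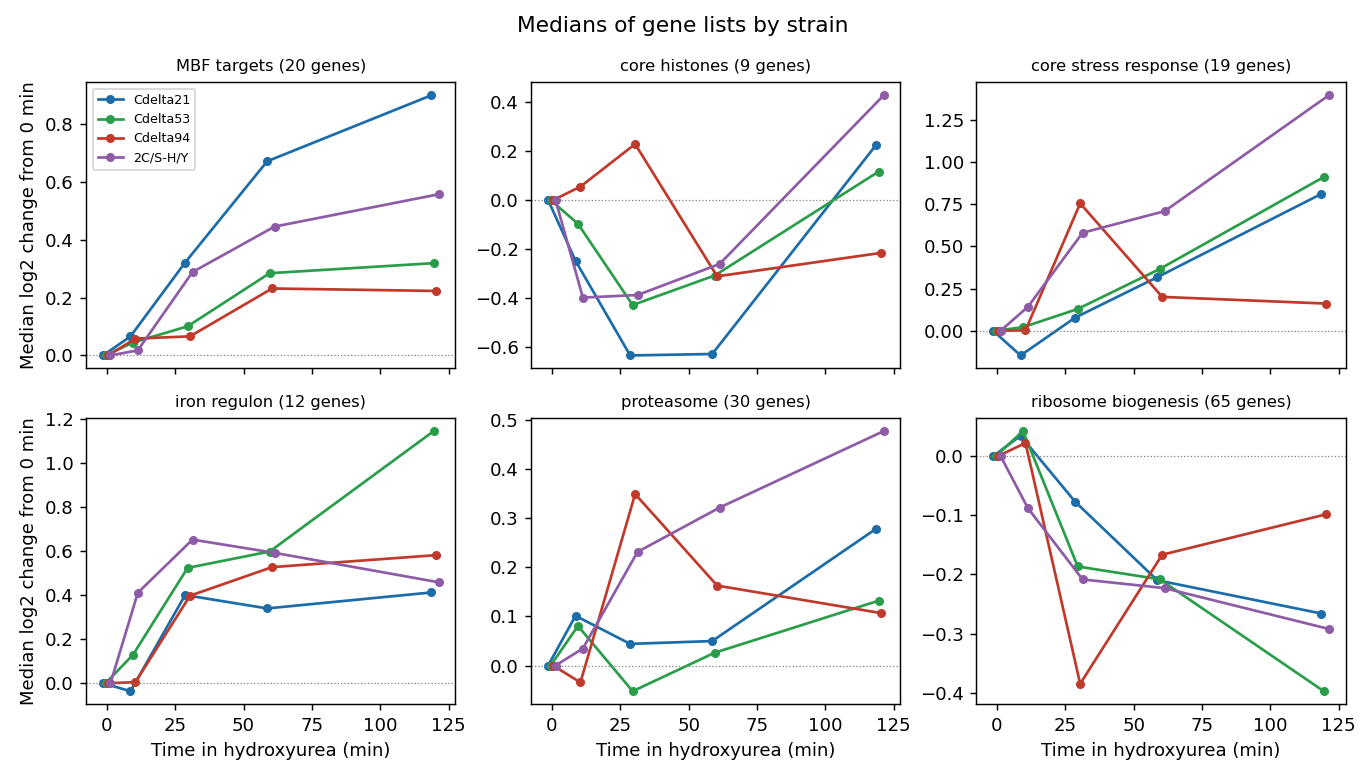
Median log2 change from 0 min of the members of 6 gene lists against time in hydroxyurea (min), with a line per strain. At 120 min the stress list stands at 0.81, 0.91, 0.16 and 1.39 in Cdelta21, Cdelta53, Cdelta94 and 2C/S-H/Y.

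Within single strains, the time course was tested over all 5 times. The genes with the smallest p were gdh2, SPOM_SPAC27D7.09C and hsp16 in Cdelta21 (adjusted p = 7.33e-17, 4.84e-14 and 4.84e-14). In Cdelta53 they were frp1, gdh2 and nc-pho1 (adjusted p = 4.43e-20, 1.68e-17 and 2.45e-17). In Cdelta94 they were mfs3, frp1 and srx1 (adjusted p = 5.2e-12, 1.36e-11 and 3.62e-11), and in 2C/S-H/Y frp1, urg2 and hsp16 (adjusted p = 3.64e-21, 2.18e-16 and 4.01e-16). The core stress response rose at 120 min in 12 of 19 genes in Cdelta21, 16 in Cdelta53 (17 adjusted over the list alone) and 17 in 2C/S-H/Y, with 0 falling in each (adjusted p = 0.00623, 0.00287 and 0.0023 with an estimated correlation). The proteasome genes rose in 2C/S-H/Y in 18 of 30 cases and fell in 0 (21 and 0 adjusted over the list alone; adjusted p = 9.84e-07, and adjusted p = 0.0263 with an estimated correlation).

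The arrays labelled Cdelta94 stood apart in time. Against 0 min limma called 1210 genes in the arrays labelled 30 min, 267 at 60 min and 38 in those labelled 120 min. In the arrays labelled 30 min 15 core stress genes rose and 0 fell (median 0.76, adjusted p = 1.33e-15, and adjusted p = 0.00198 with an estimated correlation), and 41 ribosome biogenesis genes fell (45 adjusted over the list alone; adjusted p = 2.24e-13, and adjusted p = 0.00317 with an estimated correlation). In the arrays labelled 120 min the iron regulon rose in 6 genes (8 adjusted over the list alone, median 0.58, adjusted p = 1.15e-12, and adjusted p = 5.78e-06 with an estimated correlation) and the stress list in 3 (median 0.16, adjusted p = 0.000318, but adjusted p = 0.161 with an estimated correlation).

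Over the time course 1227 genes changed in Cdelta21, 2491 in Cdelta53, 1687 in Cdelta94 and 2151 in 2C/S-H/Y. With the arrays of each strain fitted alone the counts were 555, 4881, 274 and 1351 in that order, and after quantile normalization 506 genes changed in Cdelta94. These counts are affected by pairs of arrays that nearly repeat each other: the 5 Cdelta53 replicate pairs differed with an SD across probes of 0.0722 to 0.0994, and 2C/S-H/Y 30 and 60 min replicate 1 with an SD of 0.0801, against a lowest SD of 0.17 among all other pairs of arrays. With these arrays counted once, a setting chosen after the data were seen, the counts were 631 in Cdelta21, 478 in Cdelta53 and 832 in Cdelta94. In that setting each Cdelta53 pair was averaged and both 2C/S-H/Y arrays were left out, so it also holds fewer arrays. Without the Cdelta94 30 and 120 min arrays, 836 genes changed in Cdelta94.

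The next question was whether the strains responded differently. The gene with the smallest p was frp1 (adjusted p = 3.06e-16), which at 10 min had changed by 3.66 in 2C/S-H/Y and by −0.06, 0.37 and −0.07 in Cdelta21, Cdelta53 and Cdelta94. All changes in 2C/S-H/Y start from its 0 min arrays, which stood apart from its later arrays. At 120 min frp1 had risen by 4.07 in Cdelta53, 3.95 in 2C/S-H/Y, 1.43 in Cdelta21 and 1.26 in Cdelta94 (SE 0.12 each). For gdh2 (adjusted p = 2.71e-14) the changes at 120 min were 2.14, 2.68 and 2.39 in Cdelta21, Cdelta53 and 2C/S-H/Y and 0.08 in Cdelta94. For hsp16 (adjusted p = 3.62e-12) they were 3.10, 2.45 and 4.20, and −0.10 in Cdelta94. The anaphase gene slp1 (adjusted p = 6.31e-13) changed by −1.13, −1.28 and −1.81 in those strains and stood at 0.15 in Cdelta94; in the arrays labelled Cdelta94 30 min it stood at −0.90. In all, the response of 2632 genes differed between strains, and of 829 with near-repeat arrays counted once.

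Among lists, the stress response at 120 min was smaller in Cdelta94 than in 2C/S-H/Y (median difference −1.09, 15 genes lower, 16 adjusted over the list alone, adjusted p = 2.13e-15, and adjusted p = 0.00213 with an estimated correlation). It was larger in Cdelta53 than in Cdelta94 (0.74, 13 genes, 15 adjusted over the list alone, adjusted p = 1.78e-10, and adjusted p = 0.00529 with an estimated correlation). The strains did not start level for this list. Its medians against the reference at 0 min were 0.04, 0.94, 0.60 and 0.49 in Cdelta21, Cdelta53, Cdelta94 and 2C/S-H/Y. The iron regulon moved further up in Cdelta53 than in Cdelta21 (−0.77 for Cdelta21 minus Cdelta53, 9 genes lower and 0 higher, 10 and 1 adjusted over the list alone, adjusted p = 9.15e-07, and adjusted p = 0.00058 with an estimated correlation). All comparisons with Cdelta94 at 120 min rest on arrays whose time is in doubt.

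The strains were also compared with each other before hydroxyurea (2 arrays each). Cdelta94 differed from Cdelta21 by higher Tf2-11, at −4.15 for Cdelta21 minus Cdelta94, hsp16 at −3.36 and the metallothionein gene zym1 at −2.77, and by lower cdc22 at 1.98 (3.94-fold), dut1 at 1.87 and tos4 at 1.83. Cdelta94 minus 2C/S-H/Y gave 4.33 for Tf2-11 (20.1-fold), 3.67 for zym1, −3.35 for apc10, −2.54 for cig2 and −2.30 for dut1. The rep2 ratio was lower in Cdelta94 than in Cdelta21 (adjusted p = 1.11e-19) and 2C/S-H/Y (adjusted p = 1.66e-22), by no exact amount for the reason given above. In Cdelta53 the chaperone gene hsp104 was higher than in Cdelta94 by 1.95 and than in 2C/S-H/Y by 2.93, whereas pdc201 stood at −3.32 for Cdelta53 minus Cdelta94. Cdelta21 minus Cdelta53 gave 3.63 for ted1 (12.4-fold), 3.53 for mdm12 and −2.72 for hsp16, and Cdelta21 minus 2C/S-H/Y gave 2.23 for gdh2 and −3.69 for apc10, a subunit gene of the anaphase-promoting complex.

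By list, 12 of 15 chaperone genes were higher in Cdelta53 than in Cdelta94 and 0 lower (13 and 0 adjusted over the list alone, median 0.98, adjusted p = 3.88e-08, and adjusted p = 0.0197 with an estimated correlation), and 13 of 17 mating and meiosis genes were lower in Cdelta53 (median −0.76, adjusted p = 3.88e-08, and adjusted p = 0.0118 with an estimated correlation). The core histone genes were lower in Cdelta94 than in 2C/S-H/Y in 9 of 9 cases (median −1.52, adjusted p = 1.94e-06, but adjusted p = 0.122 with an estimated correlation), and higher in Cdelta21 than in Cdelta94 in 9 of 9 (median 1.20, adjusted p = 1.17e-05, but adjusted p = 0.204 with an estimated correlation). The MBF targets were lower in Cdelta94 than in 2C/S-H/Y in 10 of 20 cases and higher in 2 (11 and 2 adjusted over the list alone; adjusted p = 0.0377, but adjusted p = 0.43 with an estimated correlation).

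The counts for pairs of strains at 0 min were 3243 for Cdelta94 and 2C/S-H/Y, 3048 for Cdelta21 and Cdelta94, 2641 for Cdelta53 and 2C/S-H/Y, 2239 for Cdelta53 and Cdelta94, 2206 for Cdelta21 and Cdelta53 and 1471 for Cdelta21 and 2C/S-H/Y. With near-repeat arrays counted once, the 3 that involve Cdelta53 were 1670, 1211 and 1221. The count for Cdelta21 and 2C/S-H/Y was 742 and 925 without replicate 1 or 2 of 2C/S-H/Y at 0 min, and 792 without replicate 1 of Cdelta21 at 0 min.

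Finally each strain at 0 min was compared with the wild-type reference. In Cdelta94 zym1 was higher at 3.77 (13.7-fold), Tf2-11 at 3.76 (13.6-fold) and lsd90 at 3.37, and SPOM_SPAC2H10.01 at −3.14 and the zinc transporter gene zrt1 at −1.80 were lower. All 9 core histone genes were lower there (median −1.07, adjusted p = 0.000179, but adjusted p = 0.191 with an estimated correlation), with hhf2 at −1.38. Of 17 mating and meiosis genes 12 were higher and 1 lower (median 0.56, adjusted p = 0.000963, but adjusted p = 0.14 with an estimated correlation), with the pheromone genes mfm3 at 1.41 and mfm1 at 1.14. Of 27 DNA damage genes 16 were higher and 4 lower (median 0.31, adjusted p = 0.0074, but adjusted p = 0.437 with an estimated correlation), with rad16 at 1.15 and rad54 at 1.01.

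In Cdelta53 14 of 15 chaperone genes were higher than the reference (median 1.03, adjusted p = 8.2e-10, and adjusted p = 0.0248 with an estimated correlation), with hsp104 at 2.49 (SE 0.11), sti1 at 1.96 and ssa1 at 1.71. Of 19 core stress genes 15 were higher and 3 lower (median 0.94, adjusted p = 5.19e-08, and adjusted p = 0.03 with an estimated correlation), with hsp16 at 2.41 and the trehalose synthesis gene tps1 at 1.76. Chaperone genes were also higher in Cdelta21 (13 of 15, 0 lower) and in 2C/S-H/Y (13 higher, 1 lower). There the list had adjusted p = 4.15e-05 and 8.76e-06, but adjusted p = 0.116 and 0.0828 with an estimated correlation. In Cdelta94 4 chaperone genes were higher and 3 lower. In 2C/S-H/Y apc10 was higher at 3.83 (SE 0.12, 14.2-fold) and gdt1 at 2.75, and SPOM_SPAC2H10.01 was lower at −2.81. The copper transporter genes ctr4 at 1.87, ctr5 at 1.34 and ctr6 at 0.74 were higher there (3 of 4 on the list, adjusted p = 0.000421, and adjusted p = 0.0396 with an estimated correlation), as were 14 of 14 glycolysis genes (median 0.62, adjusted p = 8.8e-09, but adjusted p = 0.0842 with an estimated correlation) and 9 of 9 core histone genes (median 0.61, adjusted p = 0.000126, but adjusted p = 0.173 with an estimated correlation). In Cdelta21 gdt1 was higher at 3.38 (10.4-fold) and SPOM_SPAC2H10.01 lower at −2.86, and 114 of 125 ribosomal protein genes were higher (117 adjusted over the list alone; adjusted p = 7.82e-20, but adjusted p = 0.404 with an estimated correlation). Glycolysis genes (13 of 14, 0 lower) and copper transport genes (3 of 4, 0 lower) were also higher in Cdelta21. Ribosomal protein genes were also higher in 2C/S-H/Y (93 of 125, 6 lower). These lists passed there with the preset correlation and not with an estimated one. In Cdelta94 1 glycolysis gene was higher and 7 lower. Shifts that strains share against 1 reference without a dye swap may belong to the reference or the dyes, which was not tested.

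Against the reference 2698 genes differed in Cdelta21, 2864 in Cdelta53, 3371 in Cdelta94 and 2433 in 2C/S-H/Y, of which 104, 106, 247 and 56 by at least 2-fold. Leaving out 1 array gave 1623 in Cdelta21 without its 0 min replicate 1 array, 1848 to 1899 in Cdelta53 without either of its 0 min arrays and 1437 to 1541 in 2C/S-H/Y without either of its own, and counting near-repeats once gave 1430 in Cdelta53.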

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

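The tests of near-repeat arrays as separate hybridisations, of exchanged Cdelta94 labels and of a transient Cdelta94 response, and the settings that count near-repeats once or leave out the Cdelta94 30 and 120 min arrays, were chosen after the results were seen. The genes and lists in the next 2 paragraphs stand here because their response to hydroxyurea differed between strains in a test of the difference itself (limma's interaction test for genes, camera for lists). The patterns in the Cdelta94 arrays and in near-repeat arrays were seen in correlations and differences between arrays.

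The response of 2632 genes differed between strains. For frp1 the adjusted p was 3.06e-16, for nc-pho1 and gdh2 2.71e-14 each, and for SPOM_SPCC306.11 5.61e-13. For slp1 it was 6.31e-13, for mfs3 8.17e-13, and for SPOM_SPBPB10D8.01, exg1 and SPOM_SPAC3G6.05 3.00e-12 each. For hsp16 it was 3.62e-12. At 120 min nc-pho1 had changed by 1.87, 2.86, −0.10 and 1.31 in Cdelta21, Cdelta53, Cdelta94 and 2C/S-H/Y, and SPOM_SPCC306.11 by −0.65, −2.28, 0.08 and −1.98. For exg1 the changes were −0.93, −1.54, −0.05 and −2.12. At 10 min mfs3 had changed by 2.14 in Cdelta21 and −1.39 in 2C/S-H/Y, and SPOM_SPBPB10D8.01 and SPOM_SPAC3G6.05 by −1.59 and −1.45 in 2C/S-H/Y. The changes in 2C/S-H/Y share its 0 min arrays, which stood apart from its later arrays.

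Among lists, the change from 0 to 120 min in Cdelta21 minus that in Cdelta53 had a median of −0.77 for the iron regulon. Cdelta21 minus Cdelta94 gave 0.69 for the MBF targets, 0.33 for the core stress response and −0.42 for the mitotic genes. Cdelta53 minus Cdelta94 gave 0.74 for the core stress response, 0.66 for the iron regulon and −0.49 for the mitotic genes. Cdelta94 minus 2C/S-H/Y gave −1.09 for the core stress response, −0.52 for the Pap1 list and 0.63 for the mitotic genes.

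The arrays labelled Cdelta94 30 min matched the late response of the other strains more closely than those labelled 120 min did. The lowest and highest correlations with the others' mean 120 min response, across genes that are not independent replicates, were 0.614 and 0.625 against 0.224 and 0.27. Over 1927 genes that differ between 120 and 30 min in the other strains, the Cdelta94 difference turned to their direction had a median of −0.21, with 80.4% of genes opposite, and 8 of 9 core histone genes were lower in the arrays labelled 120 min than in those labelled 30 min, against 0 of 9 in each other strain. This is consistent with exchanged 30 and 120 min labels in Cdelta94. A faster, transient response in that strain cannot be told apart from it: the arrays labelled 60 min matched the late response better than those labelled 120 min, by a difference of r of 0.145, which both explanations predict. A transient response would also return the core histones to their 0 min level or above, and in the arrays labelled 120 min their median stood at −0.22, with 0 of 9 called by limma (the list had adjusted p = 9.9e-05, but adjusted p = 0.172 with an estimated correlation).

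In 6 pairs of arrays, the 5 Cdelta53 replicate pairs and 2C/S-H/Y 30 and 60 min replicate 1, the values nearly repeated each other. The highest SD of the difference among them was 0.0994, against a lowest of 0.17 among all other pairs; as the pairs were picked by this SD, it leaves separate hybridisations of like samples open. The probes without a value overlapped by at least 0.63 in these pairs and by at most 0.44 in the other pairs of the same group, which is consistent with 1 slide read more than once. No biological explanation was tested for this pattern. In the setting called counted once, the Cdelta53 pairs were averaged and both 2C/S-H/Y arrays were left out. Counted once, these arrays left 829 genes whose response differed between strains.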

How the results depend on the processing

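Counting near-repeat arrays once and leaving out the Cdelta94 30 and 120 min arrays were chosen after the data were seen; the other alternatives were planned. Of the counts, 411 stayed within 1.5 times the reported value and 32 moved. Of single genes, 6212 values kept their direction and side of the threshold, 121 lost their call and 34 gained one; of lists, 5156 kept both, 50 lost and 43 gained the call and 1 reversed. The cause was not tested unless fewer arrays explain it. Signal over background is not known for these arrays, so the limit it sets cannot be given.

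With near-repeats counted once, the genes called at 10, 30 and 60 min were 77, 603 and 1009; over the time courses of Cdelta21, Cdelta53 and Cdelta94 631, 478 and 832; for the difference between strains 829; for Cdelta53 against Cdelta21, Cdelta94, 2C/S-H/Y and the reference 1221, 1211, 1670 and 1430; and 6 MBF targets rose in Cdelta53 at 120 min. Without the Cdelta94 30 and 120 min arrays 836 genes changed in Cdelta94. Fitting the groups compared alone gave 791 at 10 min and 555, 4881, 274 and 1351 for the time courses of Cdelta21, Cdelta53, Cdelta94 and 2C/S-H/Y. After quantile normalization 844 genes were called at 10 min and 506 in Cdelta94. The MBF targets of Cdelta21 and 2C/S-H/Y then differed by −0.0832, and the chaperones at 120 min had a median of −0.0988 (adjusted p = 0.486). A replicate block gave 714 at 10 min.

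Leaving out 1 array gave 309 to 514 genes at 10 min, 742 to 1069 for Cdelta21 against 2C/S-H/Y, and 0 to 1 MBF targets in Cdelta94 at 120 min. Against the reference it gave 1623 to 2039 in Cdelta21, 1848 to 1899 in Cdelta53 and 1437 to 1541 in 2C/S-H/Y. The lone array left in a group was assumed to vary like the other groups. Robust empirical Bayes, the random block and the fit of single groups were not run for the MBF permutation test.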

Other observations

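The test of the leu1 locus and the splits with near-repeat arrays counted once were chosen after the results were seen, and the splits of all arrays were planned. At 10 min the uracil-regulated gene urg2 had changed by 4.65 in 2C/S-H/Y and 1.58 in Cdelta53. At 30 min it had changed by 5.42 and 2.81 there, against 1.09 in Cdelta21 and 1.12 in the arrays labelled Cdelta94 30 min. Across genes, which are not independent replicates, the 10 min response of 2C/S-H/Y had correlations of −0.14, 0.000497 and −0.00599 with those of Cdelta21, Cdelta53 and Cdelta94. The urg2 changes and this response of 2C/S-H/Y start from its 0 min arrays, which stood apart from its later arrays. At 120 min the correlations among Cdelta21, Cdelta53 and 2C/S-H/Y were 0.572, 0.573 and 0.506.

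Before hydroxyurea the iron regulon was lower than the wild-type reference in Cdelta94, with 9 of 12 genes lower and 1 higher (median −0.79, adjusted p = 0.0074, but adjusted p = 0.109 with an estimated correlation), among them fio1 at −1.58 and frp1 at −1.38. In Cdelta21 7 were lower and 1 higher (median −0.43, adjusted p = 0.0251, but adjusted p = 0.116 with an estimated correlation). The Sre1 genes were lower in Cdelta94 in 8 of 10 cases (adjusted p = 0.0329, but adjusted p = 0.437 with an estimated correlation), with the heme synthesis gene hem13 at −0.96.

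In 2C/S-H/Y at 0 min apc10 stood above the mean of the other strains by 3.58, rank 1 of 5004, and leu1 by 1.59, rank 4. Of the genes within 2 places of leu1 in the annotation, leu1 included, 2 were in the top 1% (apc10 and leu1), and knh4 at 0.28, top2 at −0.11 and SPOM_SPBC1A4.04 at −0.43 were not. A change at the leu1 locus in that strain may account for both, a hypothesis found in these data and tested on them.

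The arrays of each strain were also split at random between 0 min and the later time, 100 splits per time with the real one included, as a test of grouping by chance. For 10 min 1 of 100 splits, the real one, called as many genes (475, highest other 401). For 30 min it was 1 of 100 (1338, highest other 806), for 60 min 1 of 100 (1654, highest other 1007) and for 120 min 1 of 100 (2413, highest other 2328). In these splits the real grouping keeps near-repeat arrays together, which lowers its spread. The splits were therefore repeated with near-repeat arrays counted once, that is with Cdelta53 pairs averaged and both 2C/S-H/Y arrays left out. As many genes were then called for 10 min by 4 of 100 splits (real 77, highest other 128), for 30 min by 1 of 100 (603, highest other 454), for 60 min by 1 of 100 (1009, highest other 435) and for 120 min by 1 of 100 (1790, highest other 1672). At 30, 60 and 120 min no other split drawn called as many genes, and at 10 min 3 other splits did. Other splits can mix 0 min and later arrays in a group. That raises their spread if the 2 arrays of a group are technical repeats, so the splits do not exclude chance. The 2 arrays of a group may not be separate cultures, so the splits do not cover differences between cultures.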
